A study of Caenorhabditis elegans with 6 samples.

How the data were processed

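RNA sequencing libraries of whole hermaphrodites of *Caenorhabditis elegans* strain N2 were compared between control RNAi (3 libraries) and rnk-1 RNAi (3 libraries), both with replicate numbers 1, 2 and 4. Per the labels' protocols, synchronised worms at the L4 to prefertile adult stage were kept at 20 °C, total RNA was taken with RNAiso plus, and libraries were sequenced as paired ends on a NovaSeq instrument at Macrogen. The growth notes name HT115 bacteria as the food and the extraction notes name OP50, so the food is uncertain. The selection of messenger RNA, the strand setting and whether replicates came from separate cultures are not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

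Each deposited table lists 46904 gene identifiers with an expected count, a TPM value and gene lengths, per the file headers. An expected count is RSEM's estimate of the fragments from a gene, in which fragments that match several genes are shared among them, and 2.27% of the deposited expected counts were not whole at a tolerance of 0.005. The deposited TPM value divides these counts by length and by the library's sum, and between 49.7% and 54.7% of each library's TPM lay on the ribosomal RNA gene rrn-2.1. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie 0.12.9, RSEM 1.3.1 and DESeq2 1.28.1 were used with the builds WBcel235 and ce11, without a role or order for each. Shared assignment of fragments makes near-identical genes uncertain, and without a stated strand setting the reads of a gene and of an overlapping antisense gene cannot be told apart.

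Expected counts were rounded to whole numbers. Genes with enough counts were kept with filterByExpr, library sizes were scaled by TMM, and groups were compared with edgeR's quasi-likelihood F test with robust dispersion and no covariate (edgeR 4.0.16, R 4.3.3). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower, with no fold minimum. CPM values are relative to the TMM-scaled total count of the tested genes in each library, and errors are SD over 3 libraries. Gene names and coordinates came from the Ensembl release 115 annotation of WBcel235, which holds 46817 of the identifiers; 87 were absent from it, and 44017 were in a separate table of gene names. Neither source pairs the symbol rnk-1 with an identifier, so the targeted gene and its neighbours were not analysed here.

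The design, the tests, 47 gene lists and the rule for named genes were fixed before the data were examined. The rule took, among genes with adjusted p under 0.05, a mean of at least 1 CPM and the same direction in the 3 same-numbered comparisons, the 12 largest rises and 12 largest falls, and then the 4 members with the smallest p of each list that was called or held at least 2 changed members. The text prints a part of the latter, preferring members that kept their call without any 1 library and have no overlapping gene. That preference, and the naming of further members wherever a list held 5 or fewer calls, came after their values were seen.

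The lists cover stress responses, immunity, RNA decay and stress granules, mitochondria, translation, metabolism, stage, germline and tissues, and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 47 lists. Camera with an estimated correlation and fry were run beside it. Across the lists, 18 symbols matched no gene. The symbols fixed for the mitochondrial genome matched none, and its 12 annotated protein-coding genes were used in their place. Comparisons of single values used a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3.

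A floor of 3 counts corresponded to 0.0574 to 0.0711 CPM, here relative to the unscaled total count of each library. Ratios with 1 to 3 control counts carry 95% counting intervals, and these intervals and floors cover counting error only. The procedure was tested on simulated counts for 15690 genes, of which 200 were changed. It recovered 13% of 2-fold and 56% of 4-fold changes, 2 of 71 calls were false, and none of 100 unchanged lists was called. The simulated genes varied independently of each other, so the result for lists does not carry over to lists whose members vary together. Estimated correlations within the real lists reached 0.974 (sperm genes and L4 collagens).

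Alternatives were the size factors of DESeq2 (RLE), upper quartile scaling, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, an adjusted p under 0.01, glmTreat against a 1.2-fold change, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library or each replicate number. The mean of the sperm gene list as a covariate and a restriction to protein-coding genes were added after seeing the data. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.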

Results

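The series measured gene expression in whole hermaphrodites of the nematode *Caenorhabditis elegans*, strain N2, after RNA interference (RNAi), in which double-stranded RNA matching a gene lowers its transcripts. Its title concerns ribonuclease κ, an RNA-cutting enzyme, in relation to lifespan, stress granules and circular RNA. Control RNAi and rnk-1 RNAi had 3 libraries each, from worms between the last larval stage (L4) and the start of fertility. In units of 1 M, total counts were 52.3, 42.2 and 48.4 for control replicates 1, 2 and 4, and 44.1, 43.5 and 51.01 for rnk-1 replicates 1, 2 and 4. The group means of 47.6 ± 5.09 and 46.2 ± 4.16 (SD, n = 3 each) gave a two-sided exact permutation p = 0.9, where 0.1 is the smallest p that 3 against 3 libraries allow. Protein-coding genes took 89.97% to 93.63% of counts, and nuclear ribosomal RNA took 3.88% in control replicate 2 and 1.27% to 2.06% in the other libraries.

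The comparison asks which transcripts differ when rnk-1 is knocked down. The level of rnk-1 itself was not analysed here, so the knockdown was not checked against the labels.

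In rnk-1 RNAi, 2000 of the 15903 tested genes rose and 1046 fell (edgeR quasi-likelihood test, adjusted p under 0.05), so that 65.7% of the 3046 changed genes were higher. Among the fixed lists, 15 of 24 epidermal antimicrobial peptide genes, 15 of 25 autophagy genes and 7 of 20 endoplasmic reticulum stress genes rose, and of 69 cytochrome P450 genes 28 rose and 2 fell. Of 66 mitochondrial ribosomal genes 50 fell, as did 4 of 10 mitochondrial stress genes and 3 of 6 yolk genes, and of 126 cuticle collagen genes 18 fell and 2 rose. Camera called 26 of the 47 lists, 10 higher and 16 lower, and 0 with an estimated correlation (smallest adjusted p = 0.22 with an estimated correlation, 10 lists at an unadjusted p under 0.05; fry called 25). Splits of the libraries that mixed both groups had up to 22 lists called by camera at the preset correlation. Changes of at least 4-fold were found for 476 higher and 73 lower genes, and 12 of these 476 had no counts in the controls. DESeq2 called 2394 higher and 1965 lower, with 54.9% higher. For 6475 genes (40.7%) the 3 libraries of one group lay apart from the 3 of the other, against 10% by chance. The first principal component of log2 CPM held 73.4% of the variance and placed control replicates 1, 2 and 4 at -70.3, -99.0 and -42.0, rnk-1 replicates 1 and 4 at 132.6 and 88.5, and rnk-1 replicate 2 at -9.8. Without control replicate 1, control replicate 4, rnk-1 replicate 1 or rnk-1 replicate 4, the changed genes numbered 1531, 1762, 1683 and 1496. Without rnk-1 replicate 2 they numbered 4820, of which 2143 were higher and 2677 lower.

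**Figure D1:**
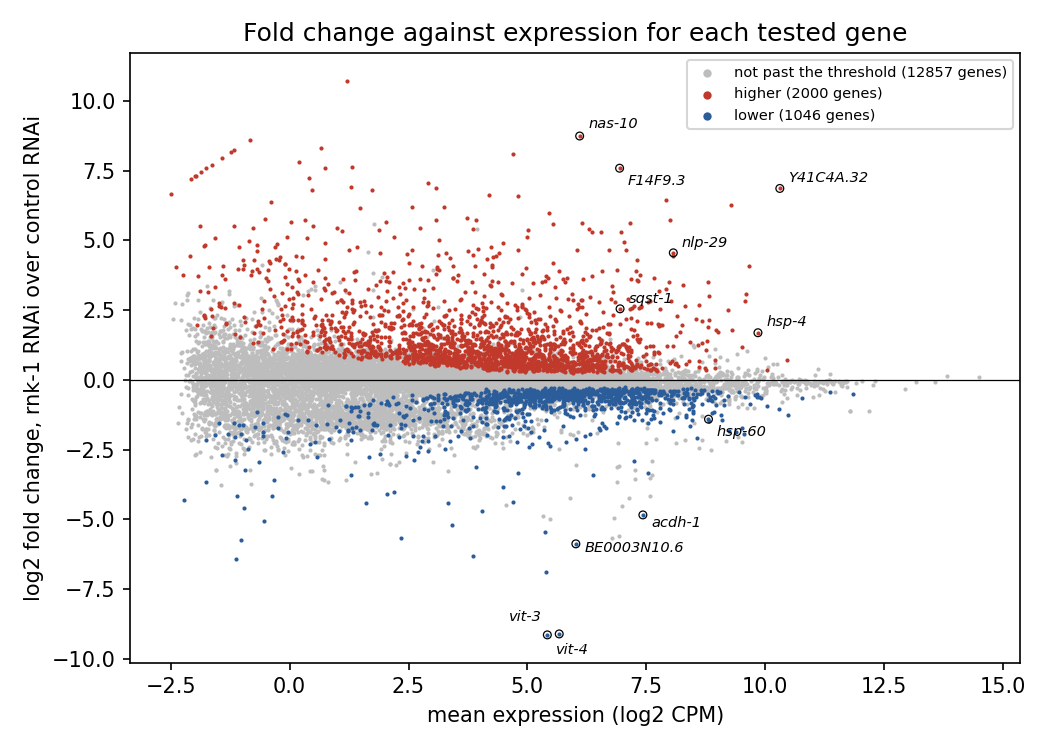
Log2 fold change of rnk-1 RNAi over control RNAi against mean expression (log2 CPM), 1 point per tested gene, from 3 libraries per group. Red points are the 2000 higher genes, blue points the 1046 lower genes and grey points the remaining genes; circled genes are named in the text, among them nas-10 at 8.74 and vit-4 at -9.14.

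The steepest rises were in genes that were almost silent in the controls. The gene nas-10, for an astacin-type metalloprotease (chromosome X, 10960914 to 10963503), rose 428-fold from 0.316 ± 0.171 to 136 ± 21.9 CPM (SD, n = 3 per group; edgeR adjusted p = 0.000433). F14F9.3 (chromosome V, 5138219 to 5141555) rose 192-fold from 1.27 ± 0.418 to 244 ± 38.8 CPM, with the same adjusted p. The insulin-like peptide gene ins-20 rose by 6.89 on the log2 scale to 16.6 ± 2.66 CPM, and the acyltransferase homologue oac-3 rose 132-fold to 14.9 ± 6.57 CPM. Another 5 of the 12 largest rises had 1 to 3 control counts over the whole group. Those were the chemoreceptor gene sre-15 at a count ratio of 429 (95% counting interval 76.7 to 17000), C09G9.8 at 311 (55.3 to 12300), B0563.9 at 222 (75.7 to 1080), the antimicrobial peptide gene cnc-7 at 226 (62.3 to 1880) and Y39H10A.1 at 179 (49.3 to 1490). F59A6.10 rose from 0.0388 ± 0.0512 to 4.79 ± 2.16 CPM and F12A10.9 from 0.184 ± 0.285 to 51.7 ± 15.7 CPM. Y41C4A.32, chosen after its values were seen for the smallest p of all genes, rose 116-fold from 21.7 ± 2.17 to 2520 ± 341 CPM (edgeR adjusted p = 0.000238). Reads could not be placed with certainty for nas-10, F12A10.9 and Y41C4A.32, which overlap antisense genes, nor for T27E4.9, a copy of the small heat shock gene hsp-16.48. T27E4.9 had no control counts and 4.50 ± 3.31 CPM in rnk-1 RNAi, at least 205-fold higher against 3 counts over the group, but summed with its near-identical copy it had 7.23 ± 8.95 and 7.05 ± 3.37 CPM (exact permutation p = 0.6).

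The 12 largest falls included 3 yolk protein genes, 3 cuticle collagen genes and acdh-1. The yolk protein genes vit-3, vit-4 and vit-5, which are near-identical, fell in sum from 271 ± 335 to 1.05 ± 1.05 CPM, lower in every rnk-1 library than in any control (exact permutation p = 0.1, the smallest possible). The gene acdh-1, for the first acyl-CoA dehydrogenase of the propionate shunt (chromosome I, 6497436 to 6499560), fell 28.6-fold from 333 ± 152 to 11.6 ± 10.2 CPM (SD, n = 3; edgeR adjusted p = 0.0114). BE0003N10.6 (chromosome III, 1056230 to 1060061) fell 58.7-fold from 127 ± 26.4 to 2.15 ± 1.46 CPM (edgeR adjusted p = 0.00275). The neighbouring genes D1014.6 and D1014.7 on chromosome V fell 79.0-fold and 36.3-fold, the nuclear receptor gene nhr-234 fell 21.2-fold and F54D10.8 fell 21.1-fold. The cuticle collagen genes col-143, col-62 and col-179 fell, with log2 fold changes of -5.67, -5.47 and -4.70. Single libraries decided several of these calls: col-143 reached adjusted p up to 0.0757 without rnk-1 replicate 1 or 4, vit-3 0.0538 without rnk-1 replicate 4, and vit-5, col-62 and col-179 up to 0.116, 0.113 and 0.132 in every fit that left out 1 library other than rnk-1 replicate 2. The genes vit-4, vit-3, col-143 and col-179 also overlap antisense genes. The expected counts of col-62 and col-179 were not whole in any of the 6 libraries, so fragments shared with other genes make both uncertain.

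**Figure D2:**
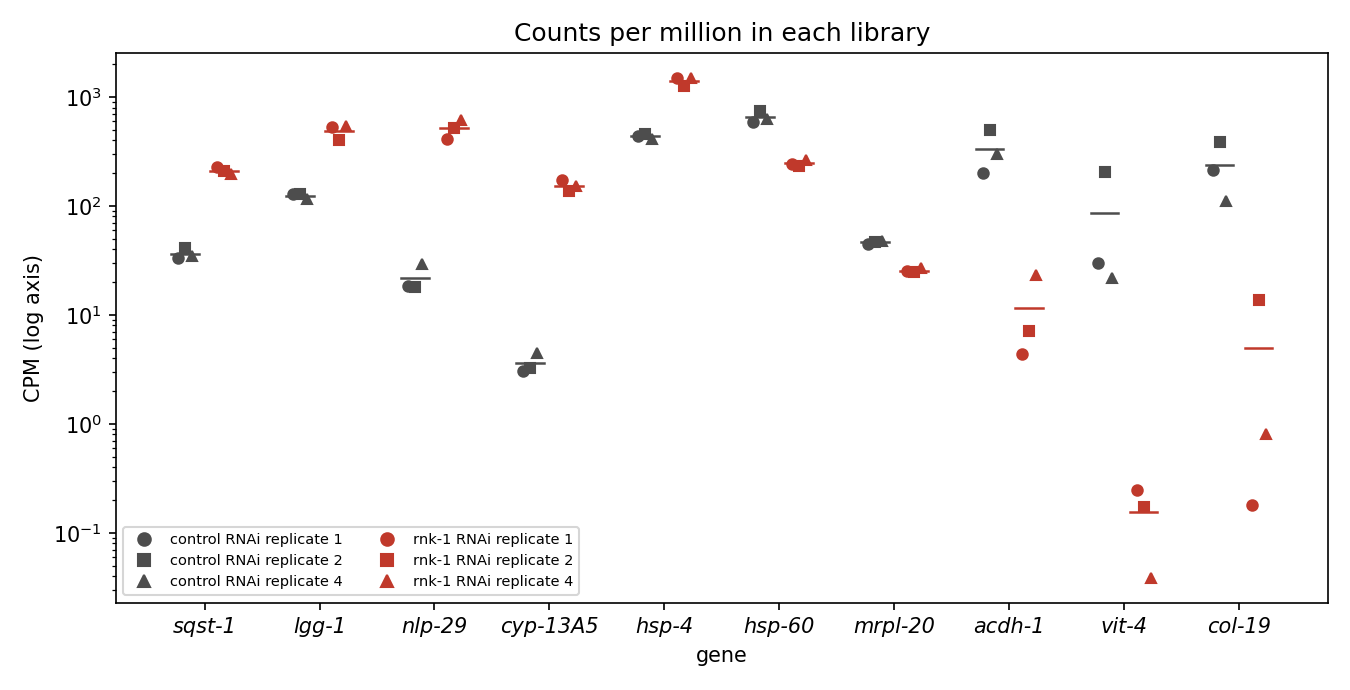
CPM on a log axis for 10 genes, 1 point per library and a line at each group mean (n = 3 control RNAi in grey, n = 3 rnk-1 RNAi in red). The libraries of both groups lie apart for hsp-4 (437 against 1412 CPM on average), hsp-60 (652 against 246) and acdh-1 (333 against 11.6), while col-19 spreads widely within rnk-1 RNAi.

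Genes for epidermal antimicrobial peptides rose as a group. Of 24 tested members, 15 were higher and 9 did not pass, or 19 higher when adjusted over the list alone. The median log2 fold change was 3.31 (camera adjusted p = 1.4e-18; adjusted p = 0.22 with an estimated correlation). The gene nlp-29, induced in the epidermis by fungal infection and wounding, rose 23.5-fold from 21.9 ± 6.5 to 514 ± 99.8 CPM (SD, n = 3; edgeR adjusted p = 0.000751). Its cluster neighbours nlp-31 and nlp-34 rose 12.2-fold and 30.6-fold, and the caenacin gene cnc-10 rose 5.34-fold. Genes of the intracellular pathogen response, which viruses and microsporidia induce, also rose: 11 of 18 were higher, 14 when adjusted over the list alone, with a median of 1.34 (camera adjusted p = 6.6e-08; adjusted p = 0.22 with an estimated correlation). Among them pals-27 rose 27.2-fold and cul-6, for a ubiquitin ligase cullin, rose 2.24-fold. Of 36 lysozyme and saposin-like genes, 12 were higher and 3 lower, 16 and 3 when adjusted over the list alone. Their median was 0.49 (camera adjusted p = 0.0059; adjusted p = 0.22 with an estimated correlation). The lysozyme gene lys-3 rose 22.5-fold from 1.23 ± 0.153 to 27.6 ± 8.96 CPM and spp-2 rose 2.93-fold, while spp-4, spp-17 and spp-23 fell. A mixed list held innate immune effectors together with the p38 MAP kinase pathway. Of its 20 genes, 6 were higher, 7 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.039, or 0.34 with an estimated correlation). The infection response genes irg-2, irg-4 and irg-5 rose 53.4-fold, 4.07-fold and 8.3-fold. The call of this mixed list was lost without control replicate 2 (adjusted p = 0.0883), control replicate 4 (0.0527) or rnk-1 replicate 1 (0.068) and with a filter of 1 CPM in 3 libraries (0.0699). Its higher members numbered 3 without control replicate 1, rnk-1 replicate 1 or rnk-1 replicate 4. Without control replicate 1, the higher members numbered 9 antimicrobial peptides, 6 pathogen response genes and 6 lysozyme and saposin-like genes; without rnk-1 replicate 4 the former 2 numbered 8 and 7, and without control replicate 4 the latter numbered 6.

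Autophagy genes rose in all 3 rnk-1 libraries. Of 25 tested members, 15 were higher and 10 did not pass, or 21 higher and 1 lower when adjusted over the list alone. The list had a median log2 fold change of 0.85 (camera adjusted p = 1.5e-11; adjusted p = 0.22 with an estimated correlation). The gene sqst-1, for the selective autophagy receptor p62, rose 5.85-fold from 36.06 ± 4.1 to 211 ± 16.43 CPM (SD, n = 3; edgeR adjusted p = 0.000433). The Atg8 homologue lgg-1 rose 3.94-fold from 124 ± 8.03 to 490 ± 75.6 CPM, and epg-4 rose 2.6-fold. The list mean per library was 0.90, 0.80 and 0.95 above the control mean in rnk-1 replicates 1, 2 and 4, and -0.08 to 0.09 in the controls. Of 20 genes for endoplasmic reticulum chaperones and the unfolded protein response, 7 were higher, also when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0017; adjusted p = 0.22 with an estimated correlation). The chaperone gene hsp-4 (BiP) rose 3.23-fold from 437 ± 20.9 to 1412 ± 137 CPM, and the stress kinase gene pek-1 (PERK) rose 2.03-fold. Of 19 genes raised by the forkhead factor DAF-16 under low insulin signalling, 9 were higher and 2 lower, 10 and 2 when adjusted over the list alone. For DAF-16 targets the median was 0.74 (camera adjusted p = 1.4e-05; adjusted p = 0.22 with an estimated correlation). The glyoxylate enzyme gene icl-1 rose 2.56-fold from 193 ± 14.3 to 494 ± 61.3 CPM, dod-3 rose 55.2-fold and the linker histone gene hil-1 rose 10.2-fold. The sestrin gene sesn-1 and the aquaporin gene aqp-1, which overlaps an antisense gene and is uncertain, fell 1.42-fold and 1.46-fold. Of these last 2 calls, 1 or neither held in each fit without 1 library, except without rnk-1 replicate 4.

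Cytochrome P450 enzymes, nuclear receptors and neuropeptides were mostly higher where they changed. Of 69 cytochrome P450 genes, 28 rose and 2 fell, 31 and 2 when adjusted over the list alone. The P450 median was 0.67 (camera adjusted p = 1.4e-08; adjusted p = 0.22 with an estimated correlation). The gene cyp-13A5 rose 42.5-fold from 3.61 ± 0.778 to 154 ± 18.7 CPM and cyp-32A1 rose 9.96-fold (SD, n = 3; edgeR adjusted p = 0.000433 and 0.000495), while cyp-25A2 and cyp-14A1 fell. Of 208 nuclear hormone receptor genes, 63 rose and 4 fell, 84 and 4 when adjusted over the list alone. The receptor median was 0.50 (camera adjusted p = 1.9e-05; adjusted p = 0.58 with an estimated correlation). The genes nhr-18 and nhr-11 rose 2.99-fold and 4.15-fold. The 4 that fell were nhr-234, nhr-235, nhr-114 and nhr-68, the latter 2 being regulators of methionine cycle and propionate genes, at 2.71-fold and 2.15-fold, with nhr-114 uncertain for an antisense overlap. Of 117 neuropeptide and insulin-like genes, 35 rose and 2 fell, 38 and 2 when adjusted over the list alone. The neuropeptide median was 0.53 (camera adjusted p = 2.3e-07; adjusted p = 0.22 with an estimated correlation). Of these 117, 10 are also in the list of epidermal antimicrobial peptides. The neuropeptide gene flp-18 rose 1.95-fold, and the insulin-like genes ins-33 and ins-27 fell. Without control replicate 1, rnk-1 replicate 1 and rnk-1 replicate 4 in turn, the higher members numbered 17, 18 and 22 P450 genes, 26, 26 and 22 nuclear receptors, and 21, 21 and 18 neuropeptides. Without control replicate 4, 41 nuclear receptors were higher.

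Genes of the mitochondrial ribosome fell together by modest amounts. Of 66 tested members, 50 were lower and 16 did not pass, or 59 lower and 1 higher when adjusted over the list alone. Across members the median log2 fold change was -0.55, with quartiles of -0.64 and -0.43 (camera adjusted p = 1.2e-17; adjusted p = 0.22 with an estimated correlation). The gene mrpl-20 fell 1.82-fold from 46.4 ± 1.18 to 25.5 ± 1.15 CPM (SD, n = 3; edgeR adjusted p = 0.00161) and mrps-23, uncertain for its overlap with the antisense gene prp-40, fell 1.98-fold. The mitochondrial chaperone genes hsp-60 and hsp-6 fell 2.65-fold, from 652 ± 83.2 to 246 ± 14.4 CPM, and 1.97-fold, from 467 ± 51.9 to 236 ± 20.6 CPM. They belong to a list of 10 genes of the mitochondrial unfolded protein response, in which 4 were lower, with dnj-10 and gpd-2, or 6 lower and 1 higher when adjusted over the list alone (median -0.40; camera adjusted p = 0.0059; adjusted p = 0.34 with an estimated correlation). This call was lost without rnk-1 replicate 2 (adjusted p = 0.0951), and gpd-2, uncertain for its overlap with mai-1, lost its call without any 1 library other than control replicate 2 (up to 0.13). The lower mitochondrial ribosomal genes numbered 28, 31, 28 and 33 without control replicate 1, control replicate 4, rnk-1 replicate 1 and rnk-1 replicate 4.

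Nuclear genes of the respiratory chain, translation factors, splicing factors and the proteasome were slightly lower as groups. Of 31 respiratory chain genes, 9 were lower, 19 when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 5.5e-05; adjusted p = 0.5 with an estimated correlation). The gene cox-6C, for a subunit of cytochrome c oxidase, fell 1.45-fold from 218 ± 12.1 to 150 ± 14.2 CPM (SD, n = 3; edgeR adjusted p = 0.017). Of 12 protein-coding genes of the mitochondrial genome, 3 were lower, also when adjusted over the list alone, namely ND6, MTCE.16 and MTCE.34 (median -0.32; camera adjusted p = 0.0068; adjusted p = 0.58 with an estimated correlation). Of 31 translation factor genes, 5 were lower, 9 when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 3e-04; adjusted p = 0.25 with an estimated correlation): eif-3.C, eif-2alpha, ife-2, eif-3.K and eif-3.H. Of 40 splicing and RNA-binding genes, 9 were lower, 13 when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0059; adjusted p = 0.22 with an estimated correlation), and snr-2, for a core snRNP protein, fell 1.37-fold. Of 33 proteasome genes, pas-4, pas-7, pbs-4 and rpn-7 were lower, 4 also when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0068; adjusted p = 0.61 with an estimated correlation). Without rnk-1 replicate 2 the calls for the mitochondrial genome (adjusted p = 0.0811), splicing (0.0811) and the proteasome (0.054) were lost. Reads of ND6, MTCE.34, eif-3.K, eif-3.H, pas-7, pbs-4 and rpn-7 are uncertain for overlapping genes. With RLE size factors 15 respiratory chain and 10 translation genes were lower, with upper quartile scaling 15 and 9, and with DESeq2 23 and 17, besides 14 splicing and 14 proteasome genes. For the mitochondrial genome fry gave an adjusted p = 0.065, and limma-trend on log2(TPM + 1) or log2(TPM + 0.1) called 0 members (5 by DESeq2, 5 by edgeR at an unadjusted p under 0.05). The genes cox-6C and snr-2 lost their calls without control replicates 1 or 4 (adjusted p up to 0.0725 and 0.0638) and eif-3.C without rnk-1 replicates 1 or 4 (0.068). At most 2 members of each list other than the mitochondrial genome were lower without control replicate 1, control replicate 4, rnk-1 replicate 1 or rnk-1 replicate 4. Without control replicate 2, 20 respiratory chain and 11 translation genes were lower, without rnk-1 replicate 2, 8 translation genes were, and ND6, MTCE.16 and MTCE.34 kept their calls only without control replicate 1 or rnk-1 replicate 2.

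Lipid metabolism changed in both directions. Of 38 genes, 11 were lower and 3 higher, 13 and 5 when adjusted over the list alone. The lipid median was -0.17 (camera adjusted p = 0.01; adjusted p = 0.58 with an estimated correlation). The fatty acid elongase genes elo-1, elo-5 and elo-6 fell 2.43-fold, 2.5-fold and 2.78-fold, elo-6 from 665 ± 89.7 to 239 ± 54.5 CPM (SD, n = 3; edgeR adjusted p = 0.00536). The lipase gene atgl-1, the acyl-CoA synthetase gene acs-2 and the lysosomal lipid chaperone gene lbp-8 rose 1.77-fold, 3.49-fold and 3.94-fold. Of 21 genes for the vacuolar proton ATPase, which acidifies lysosomes, 6 were lower and vha-5 was higher, 9 and 1 when adjusted over the list alone. The ATPase median was -0.27 (camera adjusted p = 0.016; adjusted p = 0.49 with an estimated correlation). The gene vha-5 rose 1.63-fold from 373 ± 18.4 to 609 ± 41.2 CPM and vha-20 fell by 0.36 on the log2 scale. Antisense genes overlap elo-5 and vha-5, whose values are uncertain. With upper quartile scaling 10 ATPase genes were lower, and with DESeq2 13. The lipid call was lost with fry (adjusted p = 0.12) and without control replicate 2 (0.0517) and the ATPase call without rnk-1 replicate 2 (0.0928). Without control replicate 1, control replicate 4, rnk-1 replicate 1 and rnk-1 replicate 4, the lower members numbered 7, 7, 5 and 6 for lipids and 1 in each case for the ATPase, and the higher lipid genes numbered 6 without control replicate 2 and 1 without control replicate 4.

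Camera called the lists of yolk protein and cuticle collagen genes lower in rnk-1 RNAi, although 106 of 126 collagen genes did not pass. Yolk genes mark the passage from larva to egg-laying adult, while the list of 126 holds all tested collagens named col, whatever their stage. All 6 yolk protein genes, made in the adult intestine, had lower means, 3 passed the test over all genes and 6 when adjusted over the list alone, with a median of -5.93 (camera adjusted p = 0.00042; adjusted p = 0.48 with an estimated correlation). The yolk call was lost with fry (adjusted p = 0.063), and limma-voom and limma-trend on log2(TPM + 1) called 0 of the 6 genes, against 4 by DESeq2 and 6 by edgeR at an unadjusted p under 0.05. The list mean, relative to the control mean, was -7.03, -4.72 and -6.92 in rnk-1 replicates 1, 2 and 4, and -1.27 to 2.09 in the controls. Of 126 cuticle collagen genes, 18 were lower and 2 higher, 13 and 2 when adjusted over the list alone. The collagen median was -0.66 (camera adjusted p = 4.6e-07; adjusted p = 0.22 with an estimated correlation). The gene col-77 fell 3.31-fold from 1132 ± 369 to 342 ± 60.1 CPM, while col-113, uncertain for an antisense overlap, and col-141 rose 11.5-fold and 3.1-fold (SD, n = 3; edgeR adjusted p = 0.00994, 0.00214 and 0.0115). Of all 126, DESeq2, limma-voom and limma-trend on log2(TPM + 1) called 46, 36 and 29 lower. Of 3 adult-stage collagens, col-62, uncertain for shared fragments, was lower, none without the low-count filter, and all 3 with DESeq2, with limma-voom and when adjusted over the list alone (median -5.47; camera adjusted p = 0.017; adjusted p = 0.48 with an estimated correlation). In 3 stage lists the libraries of rnk-1 RNAi differed widely from each other: their adult collagen means were -9.12, -3.62 and -7.75 for replicates 1, 2 and 4, the L4 collagen means -5.95, -0.79 and -4.06, and the sperm gene means -5.13, -0.30 and -3.44, against control values of -0.82 to 1.00, -0.53 to 0.36 and -0.83 to 0.72. For sperm genes rnk-1 replicate 2 thus lay within the control range. The lower collagens numbered 5, 9, 11, 9 and 9 without control replicates 1, 4 and 2 and rnk-1 replicates 1 and 4, col-77 lost its call without rnk-1 replicate 4 (adjusted p = 0.0518) and col-141 without control replicate 1 or rnk-1 replicate 4 (up to 0.0547). Without rnk-1 replicate 2, 47 collagens and all 6 yolk and 3 adult collagen genes were lower, without rnk-1 replicate 4 a single yolk gene was, and without any other library no adult collagen passed.

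The lists of L4 collagens and sperm genes were called as groups although no single member passed. None of 6 L4 collagen genes passed the edgeR test, over all genes or adjusted over the list alone, none had an unadjusted p under 0.05 and DESeq2 called 0, with a median of -2.24 (camera adjusted p = 0.017; adjusted p = 0.58 with an estimated correlation). The same counts of 0 held for 50 sperm genes, mostly major sperm proteins, with a median of -1.93 (camera adjusted p = 5.4e-07; adjusted p = 0.61 with an estimated correlation). The sperm gene msp-152, uncertain for fragments shared with other genes, had 36.2 ± 18.4 CPM in control and 7.64 ± 10.4 CPM in rnk-1 RNAi (SD, n = 3; edgeR adjusted p = 0.233). Without rnk-1 replicate 2, all 6 L4 collagens and all 50 sperm genes were lower. Of 25 oocyte and eggshell genes, the eggshell gene cbd-1 was lower, also when adjusted over the list alone, at 213 ± 28.3 and 102 ± 22.1 CPM, with a list median of -0.73 (camera adjusted p = 0.0012; adjusted p = 0.62 with an estimated correlation). Of 21 moulting genes, mlt-10 was lower over all genes and none adjusted over the list alone (3 at an unadjusted p under 0.05, 5 by DESeq2), with a median of -0.69 (camera adjusted p = 0.023; adjusted p = 0.61 with an estimated correlation). Reads of mlt-10 are uncertain for overlapping genes on its strand. Fry gave adjusted p = 0.092 for L4 collagens, 0.16 for sperm, 0.17 for oocyte and 0.23 for moulting genes, which ends these calls, and DESeq2 called 7 oocyte genes lower. The moulting list stood at -0.23, -0.36 and -1.12 in rnk-1 replicates 1, 2 and 4, against -0.16, 0.42 and -0.27 in the same-numbered controls. Its value in rnk-1 replicate 1 thus lay within the control range. The moulting call was lost without control replicate 2 (adjusted p = 0.12), rnk-1 replicate 2 (0.0983) or rnk-1 replicate 4 (0.0524). The gene cbd-1 lost its call without control replicate 1 or rnk-1 replicate 4 (adjusted p up to 0.0694), mlt-10 without control replicates 1 or 2 or rnk-1 replicate 4 (up to 0.0814), and 11 oocyte genes were lower without rnk-1 replicate 2.

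**Figure D3:**
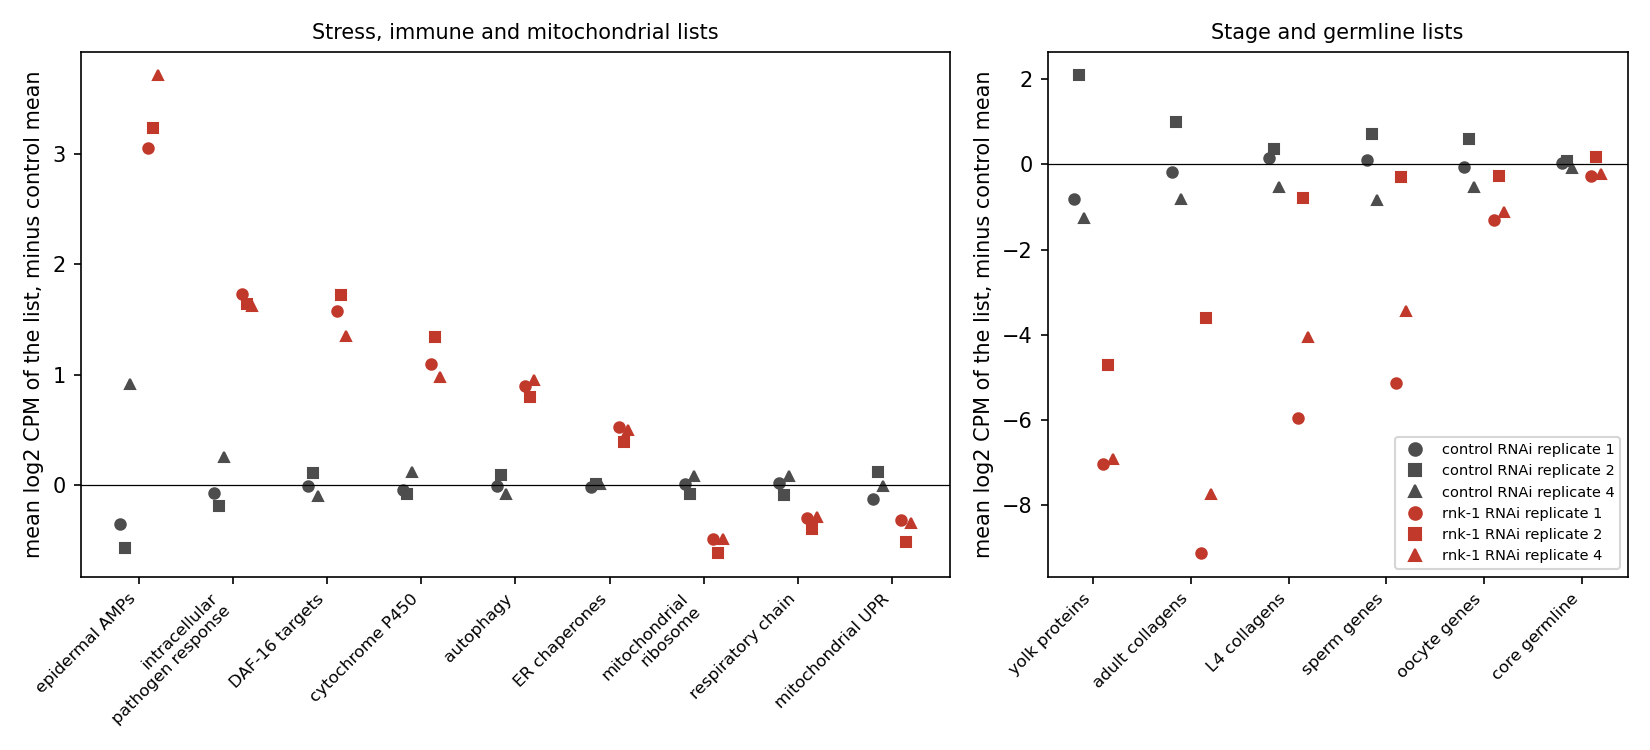
Mean log2 CPM of each list in each library minus the control mean, for stress, immune and mitochondrial lists (left) and stage and germline lists (right), 1 point per library (n = 3 per group, replicate by symbol). The rnk-1 libraries lie close together on the left (autophagy 0.80 to 0.95), while on the right rnk-1 replicate 2 lies nearer to the controls (sperm genes -0.30 against -5.13 and -3.44).

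Core germline and tissue marker lists were not called by camera, and fry called the epidermis list lower (adjusted p = 0.022). Of 32 germline proliferation and meiosis genes, mes-3, for a chromatin protein of the germline, rose 1.41-fold, 1 also when adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.48). The medians were -0.19 for 19 body wall muscle genes (camera adjusted p = 0.09), with mup-2 lower, 0.05 for 13 pharynx genes (0.65), with phat-3 and phat-6 higher, and 0.23 for 25 neuron genes (0.31), with the synaptobrevin gene snb-1 and the neuroendocrine chaperone gene sbt-1 higher. As many passed when adjusted over the list alone (1 lower for muscle, 2 higher for pharynx and 2 higher for neurons). Of 15 epidermis genes, nhr-25 rose and the collagen gene col-13 fell, with 1 higher when adjusted over the list alone and a median of -0.44 (camera adjusted p = 0.061). Of 16 intestine genes, 3 rose and 4 fell, 5 and 4 when adjusted over the list alone, and the median of -0.09 differed in sign from the mean of 0.28 and from the direction of the test (camera adjusted p = 0.88). The gut protease gene cpr-1 rose 5.61-fold from 179 ± 11.8 to 1006 ± 292 CPM (SD, n = 3; edgeR adjusted p = 0.00189), while the peptide transporter gene pept-1 and the gut actin gene act-5 fell 1.74-fold and 1.91-fold. Of 5 tested embryonic genes none passed over all genes or over the list alone (edgeR; 0 at an unadjusted p under 0.05, 0 by DESeq2), with a median of -0.17 (camera adjusted p = 0.65). The pharynx median was -0.01 under upper quartile scaling, and the epidermis list passed with no low-count filter (camera adjusted p = 0.0361). Without 1 library the epidermis list passed for control replicates 1 and 4 and rnk-1 replicates 1 and 4 (adjusted p = 0.0344, 0.0402, 0.0175 and 0.0128). The muscle list did so for control replicate 1 and rnk-1 replicate 4 (0.0174 and 0.0209) and the neuron list for control replicate 2 (0.0475). Leaving out rnk-1 replicate 2, 4 pharynx and 4 neuron genes were higher and 7 germline and 2 epidermis genes lower (2 epidermis genes also without rnk-1 replicate 4), without control replicate 2, 5 neuron genes were higher, and without control replicate 1 or rnk-1 replicate 1, 2 intestine genes were lower. The call of mes-3 was lost without rnk-1 replicate 4 and that of mup-2 without control replicates 1 or 4 or rnk-1 replicate 1. Antisense genes overlap nhr-25 and sbt-1, which are uncertain. The genes phat-3, phat-6 and snb-1 lost their calls without control replicate 1, rnk-1 replicate 1 or rnk-1 replicate 4, nhr-25 and sbt-1 also without control replicate 4, and col-13 without any control or rnk-1 replicate 1 (adjusted p up to 0.0791, 0.0801, 0.077, 0.0735, 0.0856 and 0.132).

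Stress granule, RNA decay and RNAi genes were not called as lists by camera, and fry called the RNA decay list (adjusted p = 0.024). Of 18 stress granule and P-body genes, the cap-binding protein gene ife-2 was lower (1.46-fold, to 78.5 ± 7.86 CPM; SD, n = 3; edgeR adjusted p = 0.0241), and none when adjusted over the list alone (4 at an unadjusted p under 0.05, 3 by DESeq2), with a median of -0.14 (camera adjusted p = 0.2). The stress granule protein genes gtbp-1 and tiar-1, chosen after their values were seen, had 140 ± 9.98 and 114.2 ± 4.59 CPM, and 110 ± 5.05 and 101 ± 3.71 CPM (edgeR adjusted p = 0.0587 and 0.34). Of 46 RNA decay genes, 3 rose and 6 fell, 3 and 10 when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.31). The endoribonuclease gene endu-1 rose 2.68-fold from 17.3 ± 0.624 to 46.4 ± 5.29 CPM, the decapping enzyme gene dcap-2 rose 1.4-fold and the decapping activator gene patr-1 fell 1.4-fold. Of 44 RNAi and Argonaute genes, sid-1, sid-3, ppw-1 and eri-5 rose and the germline Argonaute gene wago-4 fell 2.07-fold to 27.5 ± 4.19 CPM, 2 and 1 when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.9). Without rnk-1 replicate 4, ife-2, dcap-2, patr-1, sid-1, sid-3 and ppw-1 lost their calls, as did dcap-2, sid-1, sid-3, ppw-1 and ife-2 without control replicate 1, ife-2, patr-1, sid-3 and ppw-1 without control replicate 4, all but ife-2 without rnk-1 replicate 1, and ppw-1 without rnk-1 replicate 2. Without control replicate 1, control replicate 4, rnk-1 replicate 1 and rnk-1 replicate 4 in turn, 1, 3, 1 and 2 RNA decay genes were higher, 1, 1, 0 and 0 lower, against 6 with all libraries (edgeR; 13 by DESeq2 and 21 in either direction at an unadjusted p under 0.05), and 1, 1, 0 and 0 RNAi genes were higher. With RLE size factors and upper quartile scaling, 10 and 11 RNA decay genes and 2 and 2 stress granule and RNAi genes each were lower, and 2 RNAi genes were higher with the latter. Antisense genes overlap endu-1, dcap-2, tiar-1 and eri-5, which are uncertain. Lower stress granule genes numbered 2 without control replicate 2 or rnk-1 replicate 2, and lower RNAi genes 2 and 4. The adjusted p of the 6 named genes reached 0.0847, 0.0861, 0.0688, 0.0727, 0.0859 and 0.106.

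Several gene families and the lysosome list were not called by camera and held genes that rose and genes that fell. Fry called the lectin, F-box and lysosome lists (adjusted p = 0.013, 0.013 and 0.043). Of 63 UDP-glucuronosyltransferase genes, 12 rose and 9 fell, 16 and 11 when adjusted over the list alone, with a median of -0.01, a mean of 0.19 and a test direction of up (camera adjusted p = 0.92). The gene ugt-18 rose 43.2-fold from 0.30 ± 0.128 to 13.1 ± 5.19 CPM (SD, n = 3; edgeR adjusted p = 0.00201). Of 46 glutathione S-transferase genes, 10 rose and 8 fell, 14 and 13 when adjusted over the list alone, with a median of 0.03 (-0.02 with RLE size factors and -0.03 under upper quartile scaling), a mean of 0.16 and a test direction of down (camera adjusted p = 0.66). The gene gst-26 fell 2.09-fold. Of 18 genes linked to the oxidative stress factor SKN-1, 8 of them also glutathione S-transferases, 5 rose and 6 fell, also when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.61). Of 129 C-type lectin genes, 21 rose and 7 fell, also when adjusted over the list alone, with a median of 0.00 that was -0.05 with RLE size factors and -0.07 under upper quartile scaling (camera adjusted p = 0.5), and clec-7 rose 6.95-fold. Of 146 F-box genes, 23 rose and 3 fell, 19 and 2 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.072), fbxa-24 rising 12.1-fold while fbxa-72, fbxa-190 and fbxa-78, uncertain for an antisense overlap, fell. Of 29 lysosome genes, 5 rose and 3 fell, 8 and 3 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.25). The lysosomal membrane genes scav-3 and ctns-1 rose 2.25-fold and 1.69-fold and asp-13 fell 1.73-fold. Without control replicate 1, control replicate 4, rnk-1 replicate 1 and rnk-1 replicate 4 in turn, higher and lower lectins numbered 11 and 2, 14 and 3, 12 and 6, and 13 and 5, and glutathione S-transferases 3 and 7, 4 and 5, 4 and 5, and 4 and 4. In the same order, glucuronosyltransferases numbered 8 and 5, 9 and 4, 7 and 6, and 8 and 4, SKN-1 genes 2 and 3, 3 and 1, 2 and 3, and 3 and 2, higher F-box genes 8, 10, 11 and 6, and lower lysosome genes 2, 1, 1 and 1. Without rnk-1 replicate 2, 19 lectins and 15 F-box genes were lower and 3 SKN-1 genes higher, without control replicate 2, 5 glutathione S-transferases and 3 SKN-1 genes were higher, and without any 1 library other than rnk-1 replicate 2 the 3 lower F-box genes lost their calls. The F-box list passed with RLE size factors (adjusted p = 0.0364) and without control replicates 1, 2 or 4 or rnk-1 replicate 1 (adjusted p = 0.0472, 0.0357, 0.0215 and 0.0167).

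Chaperone, osmotic, hypoxia, histone and ribosomal protein lists were also not called by camera, and fry called the hypoxia list (adjusted p = 0.013). Of 17 cytosolic heat shock genes, sip-1 and hsp-12.6 rose, T27E4.9, whose reads could not be placed with certainty, was called higher, and the constitutive chaperone genes hsp-1 and hsp-90 fell 1.57-fold and 1.42-fold, 3 and 3 when adjusted over the list alone, with a median of -0.42, a mean of 0.59 and a test direction of down (camera adjusted p = 0.92). Antisense genes overlap sip-1, hsp-90, gpdh-1 and cysl-2, which are uncertain. Without T27E4.9 the mean of the other 16 genes was -0.05. The gene hsp-90 had 4339 ± 250 CPM in control and 3054 ± 207 CPM in rnk-1 RNAi (SD, n = 3; edgeR adjusted p = 0.0202). Of 8 osmotic stress genes, nlp-29 rose and the glycerol-3-phosphate dehydrogenase gene gpdh-1 fell 4.21-fold, 1 and 1 also when adjusted over the list alone, with a median of -0.17, a mean of 0.17 and a test direction of up (camera adjusted p = 0.92). Of 12 hypoxia and hydrogen sulfide response genes, cysl-2 fell 1.96-fold, and none when adjusted over the list alone (5 at an unadjusted p under 0.05, 3 by DESeq2), with a median of -0.16 (camera adjusted p = 0.2). Of 81 cytosolic ribosomal protein genes, rpl-41.1 fell 1.53-fold, and none when adjusted over the list alone (2 at an unadjusted p under 0.05, 6 by DESeq2), with a median of -0.08 (camera adjusted p = 0.069). None of 65 histone genes passed the edgeR test, over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05, 6 by DESeq2), with a median of 0.41 (camera adjusted p = 0.1). With the replicate number as a block, 24 histone genes were higher and the list was called (camera adjusted p = 0.00353). The ribosomal protein call was reached with RLE size factors (camera adjusted p = 0.0325), upper quartile scaling (0.0344) and no low-count filter (0.0498). It was also reached without control replicate 2 (7.59e-06), rnk-1 replicate 1 (0.0171) or rnk-1 replicate 4 (0.0398). The histone call was reached without control replicate 1 (0.00309) or rnk-1 replicate 2 (0.00222). In the fit without rnk-1 replicate 2, 15 histone genes were higher and 4 heat shock, 3 ribosomal protein and 2 hypoxia genes lower. The gene cysl-2 lost its call without any 1 library other than rnk-1 replicate 2, and rpl-41.1 without control replicates 1 or 2 or rnk-1 replicate 4. Without rnk-1 replicate 1, hsp-1, hsp-90 and sip-1 lost their calls, as did hsp-1 and hsp-90 without rnk-1 replicate 4 and hsp-90 and sip-1 without control replicates 1 or 4 (adjusted p up to 0.0646, 0.084 and 0.113).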

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

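The sperm gene score as a covariate and the fit to protein-coding genes were chosen only after the results were seen. The 3046 changed genes became 1697 with the sperm gene score, 1918 with glmTreat against 1.2-fold and 1206 at an adjusted p under 0.01, the 2000 higher genes 1160 with the score and 885 at 0.01, and the 1046 lower genes 537 with the score, 534 with glmTreat, 321 at 0.01 and 1965 with DESeq2. Fewer libraries gave 264 to 5216 changed, 232 to 2572 higher and 32 to 2677 lower genes, the lowest without replicate 1 or 4 and the highest without rnk-1 replicate 2 or without replicate 2 in both groups; the cause of the settings' differences was not tested. The labels do not say that a replicate number marks a shared culture, so the main fit did not pair libraries. Same-numbered libraries deviated together with r = 0.06, 0.50 and 0.41 for numbers 1, 2 and 4, which leaves pairing open. With the replicate number as a block 3158 genes changed, 2588 of them shared, and 4 of the 6 libraries correlated best with the other library of their number. The 26 list calls became 21 to 30 in other settings, 25 with fry, of which 19 were shared, and 0 with camera under an estimated correlation (10 at an unadjusted p under 0.05). Over 3761 values of 171 named genes, 3150 kept direction and side of the threshold, 535 no longer passed, 76 newly passed and 0 changed sign. Most of these genes were picked from the same data for large folds or small p, so a kept sign was likely beforehand. Of 145 named genes with a call, 97 kept it in every fit without 1 library. Over 416 values of called lists, 387 kept both, 29 no longer passed and 0 changed sign. Those 416 leave out fry and the estimated correlation. Fry lost yolk (adjusted p = 0.063), sperm (0.16), oocyte (0.17), mitochondrial genome (0.065), lipid (0.12), L4 collagen (0.092) and moulting genes (0.23) and gained epidermis (0.022), F-box (0.013), hypoxia (0.013), lysosome (0.043), RNA decay (0.024) and lectin genes (0.013). With the score, the calls of sperm (adjusted p = 0.418), oocyte (0.226), lipid (0.19), ATPase (0.0535), L4 collagen (0.0535) and innate immune and p38 genes (0.225) were lost. With the block, that of the innate immune and p38 genes was lost (0.105). Calls were gained for F-box (0.018), muscle (0.027) and ribosomal protein genes (0.000828) with the score, and for histones with the block (0.00353), where 24 of 65 histone genes were higher.

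Lists without a call changed the sign of their median as follows, and the cause was not tested. With the sperm gene score, medians were -0.05 for histones, -0.002 for neuron, 0.199 for core germline, -0.123 for pharynx, -0.035 for glutathione S-transferases, 0.332 for heat shock, 0.407 for osmotic stress and 0.009 for glucuronosyltransferases. Lectins had -0.046 with RLE size factors, -0.065 with upper quartile scaling, -0.017 with the 1 CPM filter and -0.014 for protein-coding genes. Glutathione S-transferases had -0.016 with RLE and -0.025 with upper quartile scaling, where pharynx had -0.009. Without 1 library or 1 replicate number, the lowest and highest medians were -0.243 and 0.016 for core germline, -0.046 and 0.127 for lectins, -0.017 and 0.263 for pharynx, -0.029 and 0.291 for glutathione S-transferases, -0.143 and 0.031 for intestine, -0.573 and 0.37 for heat shock, -0.497 and 0.04 for osmotic stress and -0.123 and 0.086 for glucuronosyltransferases.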

Other observations

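The gene classes, the list of purine, folate and methionine genes, the propionate shunt genes, the sperm gene score as a covariate and the tests on core germline, yolk and collagen genes were chosen only after results were seen. Transthyretin-like genes, a nematode family of small secreted proteins, were mostly higher where they changed: 28 of 50 rose, with a median log2 fold change of 0.66 (camera adjusted p = 5.3e-17 over 201 classes of at least 8 members named by their prefix; adjusted p = 0.62 with an estimated correlation). The gene ttr-32 rose by 3.09 on the log2 scale to 109 ± 15.8 CPM and ttr-51 rose 6.13-fold from 46.8 ± 5 to 287 ± 26.4 CPM (SD, n = 3; edgeR adjusted p = 0.000433 for both; both overlap antisense genes and are uncertain). Of 8 sma genes, named for small body size and partly of the TGF-beta pathway, 5 rose, with a median of 0.60 (camera adjusted p = 0.011; adjusted p = 0.62 with an estimated correlation), among them the Smad gene sma-4 at 2.01-fold. Of 31 vps genes, for vacuolar protein sorting, 12 rose, with a median of 0.24 (camera adjusted p = 0.0099; adjusted p = 0.84 with an estimated correlation).

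Genes of purine synthesis and salvage, the folate cycle and the methionine cycle were lower as a group, tested on members other than those whose small p-values had drawn attention to these pathways. Of these 33 genes, 15 fell, with a median of -0.51 (camera p = 2.84e-07; p = 0.015 with an estimated correlation; neither adjusted over lists). They were measured in the same libraries as the noticed members and may vary together with them, so the test is not independent support. Chosen after their values were seen, the purine salvage gene hprt-1 fell 2.5-fold from 192 ± 8.21 to 76.9 ± 1.1 CPM, the methionine cycle genes ahcy-1 and sams-1 fell 2.4-fold and 3.52-fold, and the folate gene mthf-1, uncertain for an antisense overlap, fell 2.08-fold (SD, n = 3; edgeR adjusted p = 0.000526, 0.0012, 0.00612 and 0.00234). As a hypothesis, the fall of acdh-1 belongs to a fall of the whole propionate shunt: the other 4 shunt genes had a median of -0.81, between the bounds of -1 and -0.3 set for the test, which left this undecided. Tested as a set, they were lower by camera with its preset correlation (p = 0.000112), but not with an estimated correlation (p = 0.0766), and the exact permutation p of their mean log2 CPM was 0.1, the smallest possible with n = 3. Of the set, hphd-1, ech-6 and hach-1 fell by 1.42, 1.02 and 0.59 on the log2 scale and alh-8, uncertain for an antisense overlap, had -0.18 (edgeR adjusted p = 0.00243, 0.00246, 0.00554 and 0.185). Methionine cycle and propionate shunt genes are known to respond to vitamin B12 from the bacterial food, which the labels name in conflicting ways, so a difference in food between the groups stays open and untested.

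The lower lists of yolk, cuticle collagen and sperm genes in rnk-1 RNAi were weighed against stage at harvest and a lower germline share. No single sperm gene passed, and fry did not call that list (adjusted p = 0.16). Across tested genes other than the sperm list, the slope on the sperm gene score within the 3 controls was compared with the fold change of rnk-1 RNAi. The Spearman rho was -0.36, below the bound of -0.2 set for a difference in stage. In 100 simulated unchanged groups against the same controls it was -0.05 to -0.01. The same 3 controls enter both sides of this comparison. These simulations do not show how far rho varies between real unchanged cultures, so they give no measure of chance for -0.36. A median of -0.06 for core germline genes argued against a lower germline share over the 3 rnk-1 libraries together. Their core germline means were -0.27, 0.17 and -0.22 in replicates 1, 2 and 4, and the oocyte list had a median of -0.73. Without rnk-1 replicate 2 the core germline median was -0.24 with 7 of 32 genes lower, so a lower share in replicates 1 and 4 stays open. With the sperm gene score as a covariate, cuticle collagens went from -0.66 to -0.80 with 26 genes lower (camera adjusted p = 2.2e-13, or 0.3 with an estimated correlation). This argues against the stage trend that this score follows as the whole cause for these 126 genes. Among stage-specific collagens, the adult list went from -5.47 to -3.55 (2.2e-09; 0.16 with an estimated correlation) and the L4 list from -2.24 to -0.61 and lost its call (0.054; 0.72). Yolk genes went from -5.93 to -3.49 (camera adjusted p = 0.0029; adjusted p = 0.53 with an estimated correlation) and 1 of 6 was lower against 3, which leaves that trend open for them and for L4 collagens, while the sperm list makes up the score and cannot be tested this way. As a part of the other falls it stays open too, as do a difference in development that sperm genes do not follow, from harvest time or from rnk-1 RNAi, and another effect of rnk-1 RNAi.

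Higher autophagy genes were weighed against stage and scaling. The smallest list median relative to the median of all tested genes over 3 scalings was 0.83. A change of scaling shifts all genes about alike, so this value cannot tell the scalings apart. The list median itself was 0.8 with RLE size factors and 0.79 with upper quartile scaling, which argues against the choice among these scalings as the whole cause. With the sperm gene score as a covariate the list median was 0.93 (camera adjusted p = 5.4e-08; adjusted p = 0.16 with an estimated correlation). This argues against the stage trend that this score follows as the whole cause. This score does not capture every difference tied to stage. The score of rnk-1 replicate 2, at 3.28, lay within the control scores of 2.76 to 4.31. Its summed vit-3, vit-4 and vit-5 level was 2.26 CPM, against 65.4 CPM or more in the controls. A difference in development that sperm genes do not follow stays open, as do an effect of rnk-1 RNAi and a difference in food or culture.

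Lower mitochondrial ribosomal genes were weighed in the same way. With the sperm gene score the list median was -0.64, against -0.55 without it (with the score, camera adjusted p = 2e-17, or 0.3 with an estimated correlation). Relative to the median of all tested genes, the list median nearest 0 over 3 scalings was -0.57, which likewise cannot tell the scalings apart. The list median itself was -0.6 with RLE size factors and -0.61 with upper quartile scaling. These values argue against the choice among these scalings as the whole cause. Lower genes numbered 32 of 66 with the score, against 50 without it. The rule set later for yolk and collagen genes allows this count a cut of at most 1.5 times, which the list exceeds. By its median, the stage trend that this score follows is argued against as the whole cause, while by that rule it stays open. The design has no group that separates an effect of rnk-1 RNAi from a difference in food or culture, which stay open. A difference in development that sperm genes do not follow stays open as well.

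The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For changed genes, 1 split reached the real value of 3046, and the highest of the other splits was 0 (edgeR; at an unadjusted p under 0.05, 5182 genes in the real split and at most 1064 in the others). For lists, 1 split reached the real value of 26, and the highest of the other splits was 22 and the lowest 12. Camera at the preset correlation thus called many lists also where the groups were mixed and no gene passed, so its adjusted p-values for lists overstate the evidence.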
